A study of Homo sapiens with 15 samples.

How the data were processed

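Transcript levels were measured on one-colour oligonucleotide arrays in 15 RNA samples of hPNE/hTert stable lines, per the labels. Total RNA was extracted with Trizol from exponentially growing cells, labelled with Cy3 and hybridised, 1 sample to an array. Groups were taken from the sample labels: GFP control (3 arrays), DNMT1 (4), DNMT3A (4) and DNMT3B (4). Each array holds 58717 spots of genes and transcripts and 4259 control spots, for 50599 different probes, of which 902 have 10 spots each.

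The deposited scanner files give the spot intensity in several forms. The processed intensity had its background subtracted and spatial trends removed by Agilent Feature Extraction 10.10.1.1, per the file headers, and was not normalized between arrays. The mean, median and local background intensities are pixel brightness as scanned, per the file headers. Probe coordinates are on hg19, per the file headers. The authors also deposited log2 values for 31018 of the probes, with 71 empty values, and limma is named beside Feature Extraction in the submitters' processing notes. What was done to that table is not given in the sources used here, so each column was set against the scanner values of its array. The columns share nearly 1 distribution (medians of 7.56 to 7.57) and follow the log2 median intensity without background subtraction (r across probes of 0.99987 to 0.99999, slopes of 0.985 to 1.02), against r of 0.985 to 0.988 with the processed intensity. This comparison settles the log2 scale, the direction and that genes were not centred; the filter that chose its probes stays unknown.

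For the main values, control spots and spots marked as outliers were left out, the log2 processed intensity was taken, the spots of a probe were averaged and each array's 75th percentile was subtracted. Probes well above background on every array of at least 1 group were kept, which gave 28911 probes, 58 of them with a missing value, and 0 spots of these were saturated. Each kept probe was fitted with limma 3.58.1 in R 4.3.3 with the 4 group means over all 15 arrays (11 residual and 2.28 prior degrees of freedom), with eBayes and Benjamini-Hochberg adjustment over all probes of a comparison. An adjusted p under 0.05 counts as called, and all tests are two-sided. Files were read with jsonlite 2.0.0 and version 1.17.8 of data.table, and figures drawn with matplotlib 3.10.9 in Python 3.11.15.

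Gene names were updated with a table of RefSeq genes (assembly GRCh38.p14), used for names only. Of the probes, 28174 matched by accession and 3238 by symbol or synonym, and 19187 keep the name given in the scanner files. Where a gene has several probes, the one with the highest mean over the 15 arrays stands for it. Of the genes named in the text, XIST and genes of the Y chromosome were left out. The probe sequences of the DNMT genes were read for stop codons in each frame. A probe in an untranslated region cannot see a coding transgene. The transgene sequences are not given in the sources used here.

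The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. For each comparison with GFP the rule takes, among called probes of named genes with every array of one group above every array of the other, the 10 largest rises and 10 largest falls. Between DNMT lines it takes 5 each way, and for changes shared by all 3 lines 10 each way by the smallest of the 3 changes. It adds up to 4 members of each list per comparison with the smallest p, and the genes DNMT1, DNMT3A, DNMT3B, DNMT3L, UHRF1 and TET1 to TET3. Names that are only clone, locus or reading-frame labels were passed over. The text names a part of what the rule takes.

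The 34 gene lists cover pathways, chromatin factors, imprinted, germline and homeobox genes, pancreatic cell types, and markers of endothelial, immune and neural cells that a pancreatic culture could hold. They were tested with camera over 21580 genes with complete values, with Benjamini-Hochberg adjustment over the 102 tests against GFP and, separately, over the 102 tests between DNMT lines. The lists overlap: the NF-kB and senescence lists share 10 measured genes, the mesenchymal and TGF-beta lists 8, and the epithelial and ductal lists 3. A list's genes that are below background in a group have no exact fold, so medians were also taken with such genes at their bound. Of the 67 called list tests, 28 have such a member and 7 medians moved, and both values are given for those described in the text.

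Slides were tested as batches, as a block and within each slide. The alternatives were the median in place of the 75th percentile, quantile normalization, normexp (offset 50) on the mean and background intensities with quantile normalization, the authors' deposited log2 table, no filter on dim probes or a filter over all 15 arrays, and only the 2 groups compared. Others were eBayes with trend and robust fitting, a plain t-test per probe, a limit of 2-fold, 1 probe per gene, the mean of a gene's probes, camera with an estimated correlation, fry, the replicate number as a block and each array left out in turn.

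The labels number the arrays in 2 ways, by replicate in the title and by a code from 2 to 5 in the description, and the numbering differs for GFP replicate 3. The labels do not tie a number to a shared day or batch, so pairing was checked by correlating deviations from the group means. For the code numbers of the DNMT3B and GFP arrays all 3 pairs passed 0.1 (0.12 to 0.21). Each code is a row of a slide, so position and harvest cannot be told apart. With the code as a block, DNMT3B against GFP had 2545 called probes in place of 1975 and lost no list call. In the other comparisons, and for the title numbers, at least 1 pair stayed under 0.1.

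The fit was tested on simulated arrays with 50 probes changed by each known amount among 28911. For DNMT1 against GFP, 38% of probes changed by 0.5 on the log2 scale were called, 90% of those changed by 1, 100% of those changed by 2 and 84% of those changed by -1, and 11 unchanged probes were called. For DNMT3A the shares were 54%, 94%, 100% and 90% with 9 unchanged probes called, and for DNMT3B 44%, 84%, 96% and 88% with 10. Overlaps between comparisons with GFP were set against simulations of unchanged groups that share the same GFP arrays.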

Results

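Genome-wide transcript levels were measured in hTERT-HPNE cells (hPNE/hTert in the labels), an established line of human pancreatic duct-derived cells immortalised with telomerase. Stable lines had been made by lentiviral transduction and puromycin selection to overexpress GFP or 1 of 3 DNA methyltransferases. DNMT1 maintains methylation after replication, and DNMT3A and DNMT3B set it de novo. The series held 15 one-colour arrays, with n = 3 for the GFP control line and n = 4 for each of the DNMT1, DNMT3A and DNMT3B lines, all harvested in exponential growth. Each transgene was represented by 1 stable line, so a difference between lines carries both the transgene and whatever else separates the lines. The labels call the arrays of a group biological replicates without saying whether they came from separate cultures, and p-values therefore measure only the spread between arrays of 1 line, which may be technical.

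The arrays lay on 2 slides. Slide 1 carried 2 arrays of every group, and slide 2 carried 1 GFP array and 2 arrays of each DNMT line. The 75th percentile of the processed intensity ran from 259 to 338 over the 15 arrays, and 55.7% to 60.4% of probes were well above background. In all, 28911 probes for 21580 genes with complete values were well above background on every array of at least 1 group and were tested. The number of arrays limits the precision, with a median standard error of 0.11 for the log2 fold change of a DNMT line against GFP.

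Arrays of the same line agreed closely, with Pearson correlations across probes of 0.991 to 0.995, against 0.970 to 0.990 between lines. The leading principal component held 43.8% of the variance and set the DNMT3A arrays apart, the next held 16.9% and set the DNMT1 arrays apart, and the third held 9.30% and set the GFP arrays apart. Genes are not independent replicates, so these correlations describe the arrays only.

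**Figure D1:**
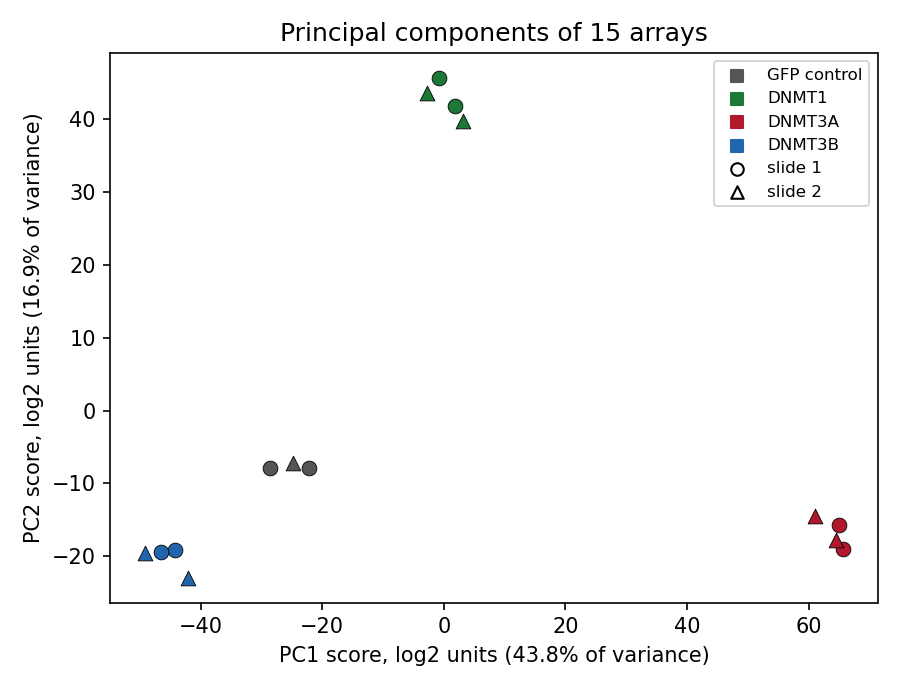
Position of each of the 15 arrays on the leading 2 principal components of the 28911 tested probes, in log2 units after scaling to the 75th percentile. Colours mark the 4 lines and symbols mark the 2 slides, and arrays of a line lie together whichever slide carried them.

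The DNMT transcripts were read first. The probe for DNMT1 (chromosome 19, 10244023 to 10244082, hg19) gave a log2 fold change of -0.13 ± 0.09 in the DNMT1 line against GFP (limma adjusted p = 0.43, n = 4 and n = 3). Its sequence holds a stop codon in 3 of 3 reading frames, so it would not see a transgene of coding sequence alone. The DNMT3B probe (chromosome 20, 31397064 to 31397123) differed by 0.03 ± 0.08 in the DNMT3B line (adjusted p = 0.88), and its sequence, with stop codons in 2 of 3 frames, does not settle whether it would see the transgene. DNMT3A was 0.33 ± 0.08 higher in the DNMT3A line at its brightest probe, with stop codons in 0 of 3 frames (chromosome 2, 25456415 to 25456474, adjusted p = 0.0052). It was 0.38 ± 0.09 higher at a neighbouring probe with stop codons in 3 of 3 frames, which would not see a transgene of coding sequence alone. Open frames do not place the brightest probe in coding sequence, so whether it would see the transgene is not settled. A further DNMT3A probe, of another transcript, fell by 0.43 ± 0.11 (adjusted p = 0.013) and by 0.63 in the DNMT1 line (0.0023). The rise at the brightest DNMT3A probe was no longer called with arrays centred on their median (0.22, adjusted p = 0.21), within slide 1 (0.36, adjusted p = 0.051) or within slide 2 (0.28, adjusted p = 0.46), with a range of 9.3e-04 to 0.46 over its alternatives. Among genes of the same machinery, TET1, which oxidises 5-methylcytosine, fell in the DNMT3A line by 0.47 ± 0.10, adjusted p = 0.0032 at its brightest probe, a call lost within slide 1 (-0.33, adjusted p = 0.11). In the DNMT1 line 2 dimmer TET1 probes fell by 0.49 ± 0.11 and 0.64 ± 0.18 (adjusted p = 0.013 and 0.037), and the brightest stood at -0.20 ± 0.10 (adjusted p = 0.25).

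Changes are given as log2 fold change ± standard error, with n = 4 arrays per DNMT line and n = 3 for GFP, and limma's adjusted p. Where a probe was not well above background on any array of the dimmer group, only a lower bound of the fold is given. It sets the brighter group's mean against, on each dim array, the higher of the probe's own signal and the lowest signal among probes well above background. Unless an array count is given, a named probe was well above background on all arrays of both groups. Where a count is given, the other arrays enter with their signal as read, so the fold is approximate, and with 1 such array no fold is given. Of the 223 called gene changes named in the comparisons, 223 were called with the slide as a block, 211 within slide 1 and 164 within slide 2.

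Gene lists fixed beforehand were tested with camera at a preset inter-gene correlation of 0.01, and 33 of the 102 tests of 34 lists against GFP passed, 11 for DNMT1, 12 for DNMT3A and 10 for DNMT3B. With the correlation estimated from the arrays, camera called 0 of the 102, with 4, 6 and 2 at an unadjusted p under 0.05, and fry, which does not set a list against other genes, called 13, 21 and 8. As many list calls arose in 5 of 100 regroupings of the arrays, the real one included, so chance was not excluded for the number of lists called. Each list's median log2 fold change is followed in brackets by its value with the slide as a block, within slide 1 and within slide 2. The sign of the median was kept in all 3 for 32 of the 33 calls, and each call lost within a slide is named with its list. The single GFP array on slide 2 is there assumed to vary like the other groups.

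In the DNMT1 line, BATF, a transcription factor of the AP-1 family, was 142-fold higher than in the GFP line (log2 fold change 7.15 ± 0.14, adjusted p = 2.4e-12; probe at chromosome 14, 76013251 to 76013310, hg19). CCL2, a monocyte chemoattractant, rose by 4.84 ± 0.19, adjusted p = 3.0e-09 (28.7-fold; chromosome 17, 32584050 to 32584109), and TUBA4A, an alpha-tubulin, by 4.76 ± 0.22 (27.1-fold). The keratin KRT17 was at least 7.55-fold (adjusted p = 5.3e-06) lower, and KRT14 fell by 4.36 ± 0.33, with 3 of 4 DNMT1 arrays well above background. The metalloproteinase inhibitor TIMP3 was at least 11.4-fold (adjusted p = 4.5e-07) lower and CCN3, a matricellular protein, at least 17.3-fold (adjusted p = 4.6e-08) lower.

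The other large rises were in ANGPTL2, a secreted angiopoietin-like protein (at least 42.1-fold, adjusted p = 5.0e-08), LIMCH1, a regulator of actomyosin (at least 16.3-fold), ZNF662 (at least 11.7-fold), HSD17B2, which oxidises estradiol (at least 9.82-fold), ACTRT3, an actin-related protein (at least 8.85-fold), and PDLIM3, a LIM protein that binds actinin (at least 6.16-fold). DPYSL3, a collapsin response mediator, rose (adjusted p = 1.2e-08), with 1 of 3 GFP arrays well above background. The other large falls were in COL15A1, a basement membrane collagen (at least 6.83-fold), KCTD15 (at least 5.87-fold), CES4A (at least 5.5-fold), the cysteine protease inhibitor CSTA (-3.94 ± 0.14), the adherens junction protein PLEKHA7 (-4.04 ± 0.42, 3 of 4 DNMT1 arrays well above background) and KRT16P2 (-4.19 ± 0.45, 2 of 4 arrays). KRT14, KRT16P2 and KRT17 have near-identical relatives, and their probes may share signal.

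Genes of the unfolded protein response and of ATF4, which drives amino acid supply under stress, were lower together in the DNMT1 line. Of 40 measured, 0 rose and 22 fell (0 and 23 adjusted over the list alone). Their median was -0.41 (-0.40, -0.42, -0.31), with camera adjusted p = 1.0e-14, adjusted p = 0.24 with an estimated correlation. VLDLR, a lipoprotein receptor, fell by 2.45 ± 0.13, and SLC7A5 and SLC3A2, the chains of the large neutral amino acid transporter, fell by 1.65 ± 0.10 and 0.93 ± 0.10. PHGDH, which opens serine synthesis, fell by 0.92 ± 0.11. The clustered protocadherins, neuronal adhesion proteins with near-identical members, were higher: of 16 measured, 10 rose and 0 fell (11 and 0 adjusted over the list alone). Their median was 0.57 (0.56, 0.64, 0.54), with camera adjusted p = 1.4e-09, adjusted p = 0.18 with an estimated correlation. PCDHB8 rose by 2.39 ± 0.11, PCDHB9 by 2.06 ± 0.14 and PCDHB16 by 1.89 ± 0.10.

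Matrix and epithelial genes also moved in the DNMT1 line. Among 36 targets of TGF-beta, 1 rose and 9 fell (1 and 10 adjusted over the list alone). Their median was -0.16 (-0.16, -0.19, -0.08), with camera adjusted p = 3.5e-05, adjusted p = 0.25 with an estimated correlation. They included LTBP1, which binds latent TGF-beta (-0.67 ± 0.05), LOX, a collagen crosslinker (-0.89 ± 0.11), and SKIL, a repressor of the pathway (-0.65 ± 0.08). Among 30 epithelial genes, 1 rose and 10 fell (2 and 10 adjusted over the list alone). Their median was -0.13 (-0.12, -0.14, -0.05), or -0.06 with dim members at their bound and -0.09 without DNMT1 replicate 2, with camera adjusted p = 0.014, adjusted p = 0.48 with an estimated correlation. This call was lost over probes well above background on all arrays (median -0.12, adjusted p = 0.068). At the preset correlation its alternatives gave 0.0032 to 0.068. MUC1, a membrane mucin, fell by 0.87 ± 0.09 at its brighter probe, while its other probe lay the other way, and ITGA6, an integrin of hemidesmosomes, rose by 0.93 ± 0.15. Of 46 mesenchymal genes, 2 rose and 14 fell (3 and 14 adjusted over the list alone). Their median was -0.06 (-0.06, -0.11, -0.02), with camera adjusted p = 0.015, adjusted p = 0.48 with an estimated correlation. This call was lost within slide 2, where GFP has 1 array, and without GFP replicate 2 (median -0.08, adjusted p = 0.062). The median was -0.10 without GFP replicate 3 and -0.11 without DNMT1 replicate 4. ITGA5, a fibronectin receptor chain, fell by 1.00 ± 0.08, and TNC, encoding tenascin C, rose by 3.03 ± 0.27, with 2 of 3 GFP arrays well above background. Of 36 growth factor and axon guidance receptor genes, 3 rose and 9 fell (4 and 14 adjusted over the list alone). Their median was -0.20 (-0.21, -0.21, -0.17), with camera adjusted p = 0.014, adjusted p = 0.42 with an estimated correlation. This call was lost within slide 2 and over probes well above background on all arrays (median -0.17, adjusted p = 0.13; 0.0053 to 0.13 over its alternatives at the preset correlation). Here the netrin receptor UNC5B fell by 3.05 ± 0.37, the Slit receptor ROBO2 by 1.16 ± 0.18 and the HGF receptor MET by 0.52 ± 0.09, while FGFR1 rose by 1.17 ± 0.11. The call of MET was lost within slide 1 (adjusted p = 0.17) and slide 2 (0.23).

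Cell cycle lists also shifted down in the DNMT1 line. Of 55 G2/M and mitosis genes, 0 rose and 9 fell (0 and 10 adjusted over the list alone). Their median was -0.24 (-0.25, -0.22, -0.23), with camera adjusted p = 1.3e-09, adjusted p = 0.62 with an estimated correlation. Among them fell CKS1B, which binds cyclin-dependent kinases (-0.31 ± 0.07), the spindle protein TPX2 (-0.33 ± 0.07) and cyclin A2, CCNA2 (-0.45 ± 0.10). These 3 calls were lost within slide 1 (adjusted p = 0.22, 0.23 and 0.24) and within slide 2 (0.48, 0.49 and 0.47). Of 49 G1/S and DNA replication genes, 0 rose and 2 fell (0 and 1 adjusted over the list alone). Their median was -0.18 (-0.18, -0.17, -0.15), with camera adjusted p = 1.9e-05, adjusted p = 0.73 with an estimated correlation. Of 35 ribosome biogenesis and MYC target genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone). Their median was -0.11 (-0.11, -0.13, -0.13), with camera adjusted p = 1.7e-04, adjusted p = 0.48 with an estimated correlation. Of 32 polycomb and histone methylation genes, 0 rose and 4 fell (1 and 6 adjusted over the list alone). Their median was -0.11 (-0.11, -0.14, -0.13), with camera adjusted p = 0.0055, adjusted p = 0.42 with an estimated correlation. They were led by CBX2, a polycomb chromobox protein (-0.76 ± 0.11), whose other probe lay the other way and whose call was lost within slide 1 (adjusted p = 0.12) and slide 2 (0.067). Cholesterol synthesis and SREBP target genes were shifted up. Their median was 0.25 (0.22, 0.29, 0.05), with camera adjusted p = 4.1e-04, adjusted p = 0.75 with an estimated correlation. Of 33 genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone). PMVK, of the mevalonate pathway, rose by 0.40 ± 0.06, a call lost with median centring (0.33, adjusted p = 0.065) and within slide 2 (0.28, adjusted p = 0.50). The call of the list was lost within slide 2 and without GFP replicate 1 (median 0.09, adjusted p = 0.26), and without GFP replicate 3 the median was 0.40.

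Over all probes, 3259 of 28911 passed limma at an adjusted p under 0.05 between the DNMT1 and GFP lines, 1619 higher and 1640 lower; 741 of them differed at least 2-fold, 443 higher and 298 lower. With the slide as a block 3516 probes passed, 1155 within slide 1 and 284 within slide 2, where GFP has 1 array. Centring arrays on their median gave 2540, of which 942 were higher and 1598 lower, so the balance of higher and lower depends on the scaling.

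**Figure D2:**
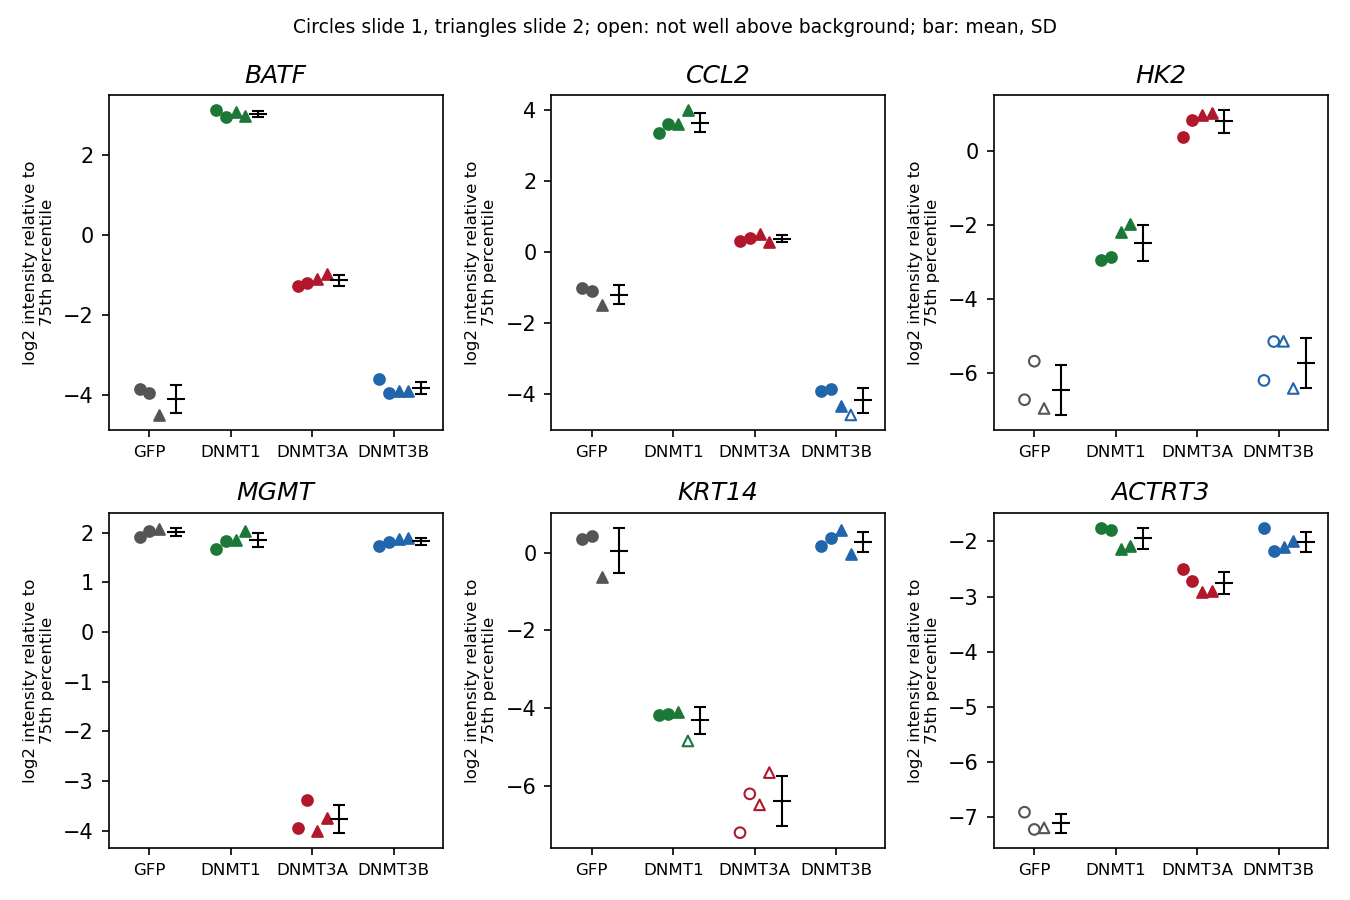
Normalized log2 intensity, relative to the array's 75th percentile, of 6 genes on each of the 15 arrays, with bars at the mean and error bars of 1 SD. Open symbols are arrays on which the probe was not well above background, where the level is only an upper bound. BATF and CCL2 stand highest in the DNMT1 line, HK2 in the DNMT3A line, MGMT and KRT14 are lowest in the DNMT3A line, and ACTRT3 is below background in the GFP line alone.

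In the DNMT3A line, HK2, which catalyses the opening step of glycolysis, was at least 59.8-fold (adjusted p = 1.0e-08) higher than in the GFP line (probe at chromosome 2, 75120331 to 75120390, hg19). MGMT, which removes alkyl groups from guanine in DNA, fell by 5.78 ± 0.13, adjusted p = 7.5e-12 (54.9-fold lower; chromosome 10, 131506282 to 131557499). The cytosolic malic enzyme ME1 was at least 38.0-fold (adjusted p = 8.3e-10) lower, the small heat shock protein HSPB2 at least 38.4-fold (adjusted p = 4.9e-10) lower and the growth factor PDGFB at least 26.6-fold (adjusted p = 1.8e-09) lower. Complement C3 rose by 4.39 ± 0.30 (21.0-fold) and BDKRB1, the bradykinin B1 receptor, by 4.30 ± 0.21 (19.7-fold).

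Other large rises were in SH3PXD2B, a podosome adaptor (at least 16.3-fold), UST, a glycosaminoglycan sulfotransferase (at least 12.2-fold), DMBT1, a scavenger receptor (at least 10.9-fold), PLXDC2 (at least 6.11-fold), ACTRT3 (at least 5.03-fold), NPFFR2, a neuropeptide FF receptor (4.74 ± 0.22), and CYP2J2, an arachidonate epoxygenase (4.19 ± 0.14, 2 of 3 GFP arrays well above background). Other large falls were in KRT14 (at least 30.5-fold, adjusted p = 9.2e-09), PLEKHA7 (at least 21.2-fold), the endodermal transcription factor SOX17 (at least 10.9-fold), GRTP1 (at least 10.5-fold), HHIP, which binds hedgehog ligands (-5.41 ± 0.20), and PREX1, a Rac exchange factor (-4.95 ± 0.16).

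NF-kB targets and inflammatory mediators rose in the DNMT3A line. Of 31 measured, 20 rose and 0 fell (20 and 0 adjusted over the list alone). Their median was 0.66 (0.65, 0.94, 0.44), with camera adjusted p = 2.3e-09, adjusted p = 0.24 with an estimated correlation. The cytokine IL11 rose by 2.47 ± 0.08, the stromelysin MMP3 by 3.08 ± 0.21, the neutrophil chemoattractant CXCL8 by 2.91 ± 0.21 and the mitochondrial superoxide dismutase SOD2 by 1.83 ± 0.13. Of 47 interferon-stimulated genes, 19 rose and 6 fell (20 and 6 adjusted over the list alone). Their median was 0.18 (0.16, 0.25, 0.08), with camera adjusted p = 0.0079 and adjusted p = 0.73 with an estimated correlation, and the call was lost within slide 2. The antigen presentation genes HLA-B, HLA-C and PSMB9 rose by 1.45 ± 0.06, 1.34 ± 0.07 and 1.13 ± 0.10. Cholesterol synthesis and SREBP targets rose without exception among called members: of 33, 22 rose and 0 fell (25 and 0 adjusted over the list alone). Their median was 0.43 (0.42, 0.65, 0.10), with camera adjusted p = 3.6e-07 and adjusted p = 0.65 with an estimated correlation, and the call was lost within slide 2. They included STARD4, a cholesterol carrier (0.67 ± 0.09), FADS1, a fatty acid desaturase (1.18 ± 0.20), and FDFT1, which makes squalene (0.61 ± 0.11). Of 16 clustered protocadherins, 12 rose and 0 fell (12 and 0 adjusted over the list alone). Their median was 1.06 (1.05, 1.14, 0.88), with camera adjusted p = 3.6e-07, adjusted p = 0.21 with an estimated correlation. PCDHB8 rose by 2.12 ± 0.11 and PCDHB6 was at least 5.88-fold higher.

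Adhesion and matrix genes were among the lists that shifted down in the DNMT3A line. Of 30 epithelial genes, 3 rose and 15 fell (3 and 16 adjusted over the list alone). Their median was -0.40 (-0.39, -0.36, -0.40), with camera adjusted p = 1.7e-04, adjusted p = 0.24 with an estimated correlation. SPINT2, a serine protease inhibitor, fell by 2.45 ± 0.13 and keratin 18 (KRT18) by 1.20 ± 0.08, while the laminin chain LAMB3 rose by 1.43 ± 0.08. Of 46 mesenchymal genes, 9 rose and 21 fell (11 and 22 adjusted over the list alone). Their median was -0.22 (-0.22, -0.20, -0.19), with camera adjusted p = 0.016, adjusted p = 0.48 with an estimated correlation. This call was lost within slide 2 and without DNMT3A replicate 4 (median -0.23, adjusted p = 0.052). ITGA5 fell by 1.35 ± 0.08, the proteoglycan decorin (DCN) by 1.23 ± 0.08 and the smooth muscle protein TAGLN by 1.27 ± 0.08, and TNC rose by 3.65 ± 0.27, with 2 of 3 GFP arrays well above background. Of 36 TGF-beta targets, 5 rose and 16 fell (7 and 17 adjusted over the list alone). Their median was -0.28 (-0.28, -0.31, -0.25), with camera adjusted p = 0.0014, adjusted p = 0.47 with an estimated correlation. LTBP1 fell by 0.80 ± 0.05 and TIMP3 was at least 10.6-fold lower. Of 24 YAP and TEAD targets, 3 rose and 10 fell (5 and 15 adjusted over the list alone). Their median was -0.22 (-0.22, -0.26, -0.23), with camera adjusted p = 0.0027, adjusted p = 0.48 with an estimated correlation. ANKRD1 fell by 4.06 ± 0.39 and IGFBP3, which binds insulin-like growth factors, by 2.58 ± 0.26. Of 24 WNT pathway genes, 3 rose and 8 fell (4 and 10 adjusted over the list alone). Their median was -0.17 (-0.18, -0.22, -0.13), with camera adjusted p = 0.018 and adjusted p = 0.21 with an estimated correlation, and the call was lost within slide 2. The transcription factor TCF7 was at least 6.4-fold lower, the secreted inhibitor DKK1 fell by 1.98 ± 0.13 and LEF1 rose by 0.93 ± 0.07.

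Of 27 tumour suppressors often methylated in pancreatic cancer, 4 rose and 12 fell (4 and 14 adjusted over the list alone) in the DNMT3A line. Their median was -0.17 (-0.18, -0.17, -0.25), or -0.11 with dim members at their bound, with camera adjusted p = 0.0016, adjusted p = 0.1 with an estimated correlation. Beside MGMT and TIMP3, CDKN2A, which inhibits cyclin-dependent kinases 4 and 6, fell by 1.37 ± 0.09 and TFPI2, a serine protease inhibitor, by 1.02 ± 0.08. Of 19 stem and progenitor markers, 3 rose and 8 fell (4 and 8 adjusted over the list alone). Their median was -0.10 (-0.11, -0.14, -0.09), or -0.07 without DNMT3A replicate 1 and -0.16 without DNMT3A replicate 3, with camera adjusted p = 0.02, adjusted p = 0.21 with an estimated correlation. The retinaldehyde dehydrogenase ALDH1A1 fell by 4.45 ± 0.10, the sialomucin PODXL by 4.57 ± 0.28 and SALL4, a zinc finger factor, by 4.13 ± 0.22, with 3 of 4 DNMT3A arrays well above background. SOX9, a factor of ductal progenitors, was at least 4.79-fold (adjusted p = 1.2e-09) higher. Of 40 unfolded protein response and ATF4 targets, 6 rose and 18 fell (8 and 21 adjusted over the list alone). Their median was -0.22 (-0.25, -0.23, -0.26), with camera adjusted p = 1.7e-04, adjusted p = 0.63 with an estimated correlation. Falls included SLC7A5 (-1.63 ± 0.10), VLDLR (-1.92 ± 0.13), CHAC1, which degrades glutathione (-2.10 ± 0.18), and CBS, of transsulfuration (-1.07 ± 0.11).

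Over all probes, 8057 passed between the DNMT3A and GFP lines, 4110 higher and 3947 lower, and 1461 differed at least 2-fold, 646 higher and 815 lower. With the slide as a block 8371 passed, 3775 within slide 1 and 1156 within slide 2. Centring on the median moved the median of all probes from 0.05 to -0.06 (a shift of -0.11) and gave 6192, of which 1890 were higher and 4302 lower.

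**Figure D3:**
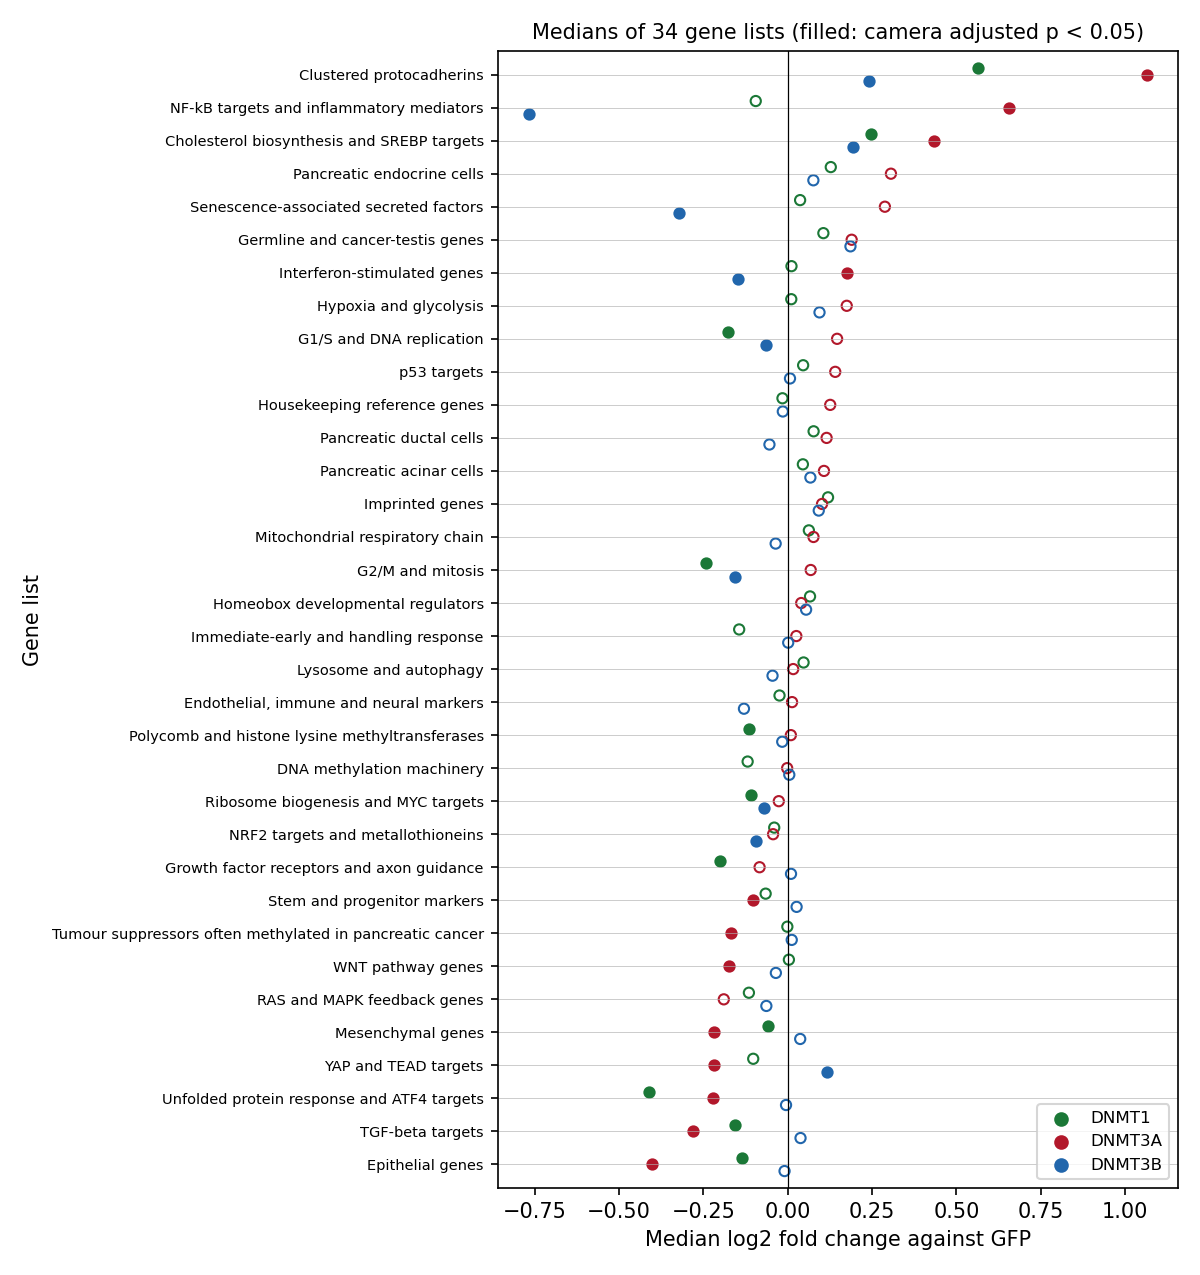
Median log2 fold change of each of the 34 gene lists in the DNMT1, DNMT3A and DNMT3B lines against GFP. Filled circles passed camera at an adjusted p under 0.05 with the preset correlation and open circles did not, and the NF-kB list lies at 0.66 in the DNMT3A line and -0.77 in the DNMT3B line.

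In the DNMT3B line, CAPG, which caps actin filaments, fell by 4.00 ± 0.10, adjusted p = 4.6e-11 against GFP (16.0-fold lower; probe at chromosome 2, 85622016 to 85622075, hg19). The chemokine CCL2 fell by 2.98 ± 0.19, with 3 of 4 DNMT3B arrays well above background, and VNN1, a pantetheinase, was at least 11.3-fold (adjusted p = 3.2e-07) lower. DPPA4, a gene of pluripotent cells, rose by 3.51 ± 0.23, adjusted p = 4.5e-07 (11.4-fold; chromosome 3, 109045928 to 109045987). The cancer-testis genes SSX1, SSX4B and MAGEA10 rose by 3.28 ± 0.18, 3.24 ± 0.20 and 3.10 ± 0.35, with 2 of 3 GFP arrays well above background for MAGEA10. The SSX genes are near-identical and their probes may share signal.

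Other large rises were in ACTRT3 (at least 8.47-fold, adjusted p = 6.8e-11), CABP1, a neuronal calcium-binding protein (at least 5.07-fold), MEGF6 (at least 3.67-fold), the pseudogene SSX8P (3.38 ± 0.32) and BEX1 (at least 1.97-fold, 3 of 4 DNMT3B arrays well above background). Other large falls were in CCN3 (at least 16.6-fold, adjusted p = 3.1e-08), CLGN, a testis chaperone (at least 8.56-fold), COL15A1 (at least 6.38-fold), SAA2, an acute phase protein with a near-identical relative (at least 5.99-fold, adjusted p = 0.0013), KCTD15 (at least 5.49-fold), LCE3A, of the cornified envelope (-4.56 ± 0.34), and the neuroligin NLGN4X (adjusted p = 9.9e-09, 1 of 4 arrays well above background).

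NF-kB targets and inflammatory mediators fell in the DNMT3B line, opposite to the DNMT3A line. Of 31 measured, 0 rose and 18 fell (0 and 22 adjusted over the list alone). Their median was -0.77 (-0.74, -0.64, -0.87), with camera adjusted p = 4.0e-20, adjusted p = 0.1 with an estimated correlation. Beside CCL2, the chemokine CXCL5 fell by 1.75 ± 0.13 and IL11 by 0.86 ± 0.08, and MMP3 was at least 2.21-fold (adjusted p = 5.0e-06) lower. The list of secreted factors linked to senescence shares 10 measured genes with this list. Of its 34, 2 rose and 13 fell (3 and 17 adjusted over the list alone). Their median was -0.32 (-0.31, -0.23, -0.44), with camera adjusted p = 2.8e-08, adjusted p = 0.21 with an estimated correlation. They include PLAU, the urokinase (-1.69 ± 0.16), and AREG, an EGF receptor ligand (-1.55 ± 0.17). Of 47 interferon-stimulated genes, 3 rose and 9 fell (3 and 14 adjusted over the list alone). Their median was -0.15 (-0.15, -0.17, -0.14), or -0.09 without DNMT3B replicate 1, with camera adjusted p = 1.7e-04, adjusted p = 0.62 with an estimated correlation. HERC5, an ISG15 ligase, was at least 2.01-fold lower, HLA-B fell by 0.57 ± 0.06 and the antiviral GTPase MX1 by 1.52 ± 0.20, while IFITM1 rose by 1.42 ± 0.22. Of 29 NRF2 targets and metallothioneins, 0 rose and 4 fell (0 and 6 adjusted over the list alone). Their median was -0.09 (-0.10, -0.11, -0.13), with camera adjusted p = 0.0026, adjusted p = 0.61 with an estimated correlation. It was -0.05 without GFP replicate 1, -0.15 without GFP replicate 2 and -0.16 without DNMT3B replicate 1. The aldo-keto reductases AKR1C3 and AKR1C1, which are close relatives, fell by 3.04 ± 0.24 and 2.23 ± 0.23, and the metallothionein MT1F by 1.00 ± 0.19.

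**Figure D4:**
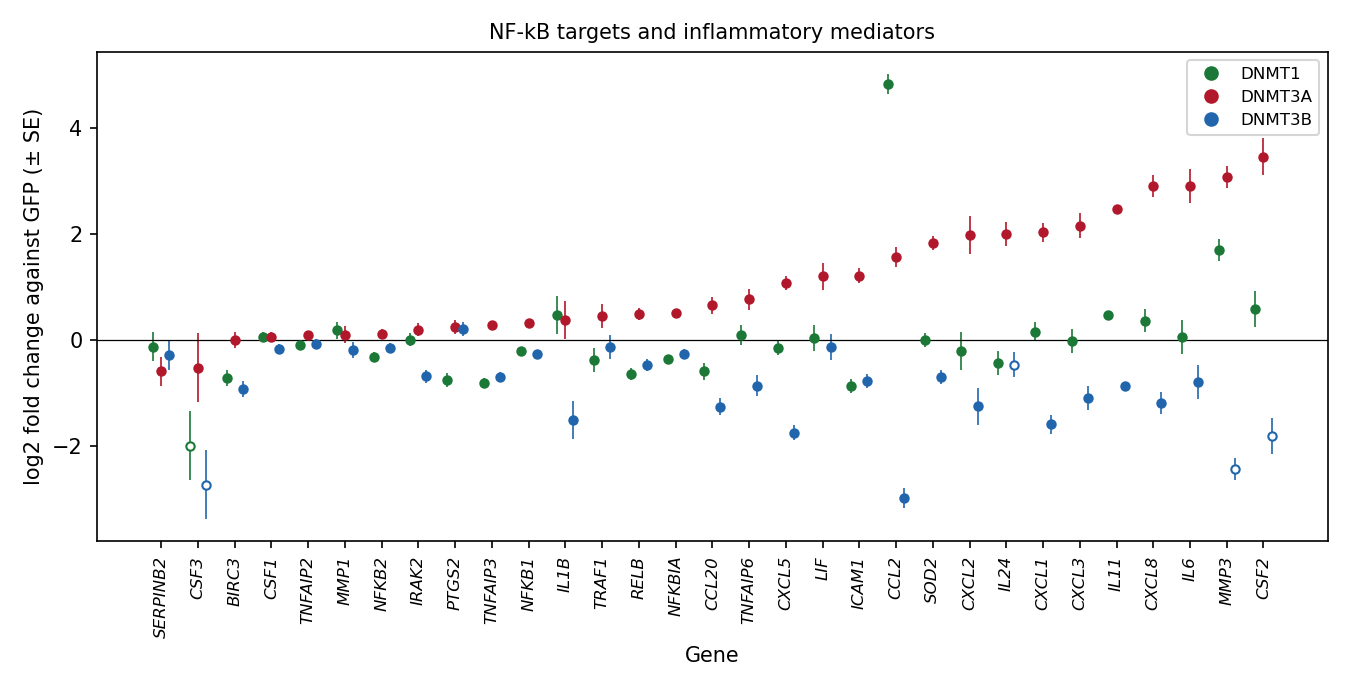
Log2 fold change against GFP, with error bars of 1 standard error, of the 31 measured NF-kB targets and inflammatory mediators in the DNMT1, DNMT3A and DNMT3B lines, ordered by the change in the DNMT3A line. Open symbols are genes not well above background on any array of 1 of the groups, whose fitted value is no exact fold, and most genes lie above 0 in the DNMT3A line and below 0 in the DNMT3B line.

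A further 6 lists passed in the DNMT3B line. Of 16 clustered protocadherins, 4 rose and 0 fell (6 and 0 adjusted over the list alone). Their median was 0.24 (0.23, 0.08, 0.44), with camera adjusted p = 0.0026, adjusted p = 0.48 with an estimated correlation and adjusted p = 0.096 within slide 1 (3.2e-04 to 0.096 over its alternatives at the preset correlation). Without DNMT3B replicate 3 the median was 0.13. PCDHB8 rose by 1.08 ± 0.11 and PCDHB6 was at least 2.56-fold higher, though not called within slide 1 or 2 alone (adjusted p = 0.057 in each). Of 55 G2/M and mitosis genes, 0 rose and 3 fell (0 and 1 adjusted over the list alone). Their median was -0.16 (-0.15, -0.12, -0.18), with camera adjusted p = 1.9e-06, adjusted p = 0.71 with an estimated correlation. Of 35 ribosome biogenesis and MYC targets, 1 rose and 1 fell (1 and 1 adjusted over the list alone). Their median was -0.07 (-0.07, -0.08, -0.08), with camera adjusted p = 0.01, adjusted p = 0.62 with an estimated correlation. ODC1, which opens polyamine synthesis, rose by 0.41 ± 0.07, a call lost with median centring (0.34, adjusted p = 0.054), within slide 1 (0.38, adjusted p = 0.12) and within slide 2 (0.49, adjusted p = 0.21). The call of the list was lost within slide 1 (adjusted p = 0.12) and without GFP replicate 2 (median -0.06, adjusted p = 0.072; 0.0015 to 0.12 over its alternatives at the preset correlation). For cholesterol synthesis and SREBP targets, 2 rose and 0 fell (0 and 0 adjusted over the list alone) of 33. Their median was 0.19 (0.19, 0.28, -0.0013), with camera adjusted p = 4.0e-04, adjusted p = 0.75 with an estimated correlation. The median turned to -0.0013 within slide 2 (adjusted p = 0.95), and the call was lost without GFP replicate 1 (0.06, adjusted p = 0.34; 1.7e-10 to 0.95 over its alternatives). Without GFP replicate 3 the median was 0.32. For YAP and TEAD targets, 4 rose and 2 fell (6 and 2 adjusted over the list alone) of 24. Their median was 0.12 (0.11, 0.17, 0.10), with camera adjusted p = 0.02, adjusted p = 0.62 with an estimated correlation. That call was lost within slide 2, with median centring (0.04, adjusted p = 0.097), without GFP replicate 1 (0.11, adjusted p = 0.088) and without DNMT3B replicate 2 (0.10, adjusted p = 0.080). For G1/S and DNA replication genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone) of 49. Their median was -0.06 (-0.08, -0.06, -0.09), with camera adjusted p = 0.03, adjusted p = 0.82 with an estimated correlation. That call was lost within slide 1 (adjusted p = 0.13), under each of 4 other scalings (adjusted p from 0.051 to 0.071), and without DNMT3B replicate 1 (-0.04, adjusted p = 0.10), DNMT3B replicate 3 (-0.07, adjusted p = 0.059), GFP replicate 2 (-0.07, adjusted p = 0.15) or GFP replicate 3 (-0.05, adjusted p = 0.10; 0.0014 to 0.15 over its alternatives at the preset correlation).

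Over all probes, 1975 passed between the DNMT3B and GFP lines, 918 higher and 1057 lower, and 504 differed at least 2-fold, 182 higher and 322 lower. With the slide as a block 2097 passed, 518 within slide 1 and 162 within slide 2. Without GFP replicate 3 the count was 1284, and centring on the median gave 1478, of which 417 were higher and 1061 lower.

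All 3 DNMT lines shared a set of changes against GFP. Among genes called higher in each, the actin-related protein gene ACTRT3 was at least 8.85-fold, at least 5.03-fold and at least 8.47-fold higher in the DNMT1, DNMT3A and DNMT3B lines. RDH13, a retinol dehydrogenase, rose by 2.09 ± 0.16, 1.78 ± 0.16 and 1.64 ± 0.16, and SSPN, a dystrophin-associated protein, by 1.59 ± 0.10, 1.22 ± 0.10 and 1.26 ± 0.10. Among genes called lower in each, MEI1, a meiosis gene, fell by 1.96 ± 0.18, 2.38 ± 0.18 and 2.15 ± 0.18, and NXF3, of the nuclear export factor family, by 2.51 ± 0.11, 2.07 ± 0.11 and 1.93 ± 0.11. COL15A1 was at least 6.83-fold, at least 6.3-fold and at least 6.38-fold lower, and KCTD15 at least 5.87-fold, at least 4.94-fold and at least 5.49-fold lower. CCN3 was at least 17.3-fold lower in the DNMT1 line and at least 16.6-fold lower in the DNMT3B line, and in the DNMT3A line it fell by 2.99 ± 0.24.

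In all, 293 probes were called in the same direction in the 3 comparisons, 145 higher and 148 lower. Independent lists would share 7.31 and 8.19, and 20 simulations of unchanged groups against the same GFP arrays, which leave out real effects, shared at most 0. For pairs, DNMT1 and DNMT3A shared 1832 probes with the same direction (881 higher, 951 lower; 230 and 224 from independent lists) and 292 with opposite directions. DNMT1 and DNMT3B shared 577 (289 and 288; 51.4 and 60.0 from independent lists) against 273 opposite, and DNMT3A and DNMT3B shared 558 (252 and 306; 131 and 144) against 681 opposite. The covariance of the log2 fold changes across probes was 0.12 for DNMT1 and DNMT3A, 0.04 for DNMT1 and DNMT3B and 0.01 for DNMT3A and DNMT3B, where the shared GFP arrays alone gave 0.02 in simulations, and the correlations were 0.498, 0.263 and 0.0689 against 0.57 simulated. Centring on the median gave 233 in place of 293, 65 higher and 168 lower. The 3 GFP arrays are too few to give 2 sets of at least 2 arrays, so part of the excess may come from the shared controls. Without GFP replicate 2 or 3 the 3-way count was 183 or 192, that of DNMT1 with DNMT3B 372 or 375, and that of DNMT3A with DNMT3B 342 or 355.

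Between the DNMT3A and DNMT1 lines, PREX1 fell by 5.79 ± 0.15, adjusted p = 1.3e-11, MGMT by 5.62 ± 0.12 and GSTM3, a glutathione transferase, by 5.18 ± 0.09 in the DNMT3A line, and HSPB2 and LIMCH1 were at least 28.2-fold (adjusted p = 4.6e-10) and at least 14.1-fold lower, with n = 4 arrays in each. CYP2J2 was at least 23.9-fold (adjusted p = 2.7e-11) higher, the adhesion receptor ADGRB3 at least 9.48-fold and PLXDC2 at least 5.73-fold; SAA2 rose by 4.88 ± 0.56 and MAGEA11, a cancer-testis gene, also rose (adjusted p = 2.1e-09), with 3 and 1 of the 4 DNMT1 arrays well above background. NF-kB targets were higher, 23 rose and 1 fell (25 and 1 adjusted over the list alone) of 31. Their median was 1.13 (1.13, 1.24, 0.96), or 1.09 with dim members at their bound, with camera adjusted p = 3.8e-12, adjusted p = 0.2 with an estimated correlation. ICAM1, a leukocyte adhesion molecule, rose by 2.09 ± 0.12 and CCL2 fell by 3.27 ± 0.17. Cell cycle genes were higher too, 34 rose and 0 fell (46 and 0 adjusted over the list alone) of 55 G2/M genes. Their median was 0.30 (0.30, 0.21, 0.41), with camera adjusted p = 8.8e-10, adjusted p = 0.6 with an estimated correlation. Of 49 G1/S genes, 27 rose and 1 fell (34 and 1 adjusted over the list alone). Their median was 0.30 (0.30, 0.21, 0.38), with camera adjusted p = 1.2e-07, adjusted p = 0.64 with an estimated correlation. HJURP, which loads centromeric histone, rose by 0.55 ± 0.08 and the helicase subunit MCM7 by 0.55 ± 0.08, calls lost within slide 1 (adjusted p = 0.11 and 0.096). Of 27 tumour suppressors, 4 rose and 14 fell (5 and 15 adjusted over the list alone). Their median was -0.33 (-0.33, -0.40, -0.31), with camera adjusted p = 9.6e-04, adjusted p = 0.1 with an estimated correlation. Of 24 WNT pathway genes, 3 rose and 10 fell (3 and 12 adjusted over the list alone). Their median was -0.27 (-0.27, -0.24, -0.19), or -0.19 with dim members at their bound, with camera adjusted p = 0.0043, adjusted p = 0.1 with an estimated correlation. DKK1 stood at -2.11 ± 0.12 and WNT5A at 1.20 ± 0.06. In all, 7339 probes differed, 3688 higher and 3651 lower in DNMT3A (7645 with the slide as a block, 2756 within slide 1, 1479 within slide 2).

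Between the DNMT3B and DNMT1 lines, CCL2 was 227-fold lower in the DNMT3B line (-7.82 ± 0.17, adjusted p = 4.8e-12), with 3 of 4 DNMT3B arrays well above background, and BATF fell by 6.88 ± 0.13. LCE3A fell by 5.99 ± 0.31, NLGN4X fell (adjusted p = 1.6e-11, 1 of 4 DNMT3B arrays well above background), and DLL3, a Notch ligand, was at least 24.6-fold (adjusted p = 6.0e-12) lower. MAGEA10 was at least 12.7-fold (adjusted p = 2.0e-07) higher, the phosphatase CPPED1 at least 11.2-fold higher, and KRT14 and KRT16P2 rose by 4.57 ± 0.31 and 4.39 ± 0.41, measured on 3 and 2 of the 4 DNMT1 arrays. Unfolded protein response and ATF4 targets were higher, 24 rose and 1 fell (25 and 1 adjusted over the list alone) of 40. Their median was 0.41 (0.41, 0.36, 0.45), with camera adjusted p = 9.9e-11, adjusted p = 0.32 with an estimated correlation. VLDLR rose by 2.04 ± 0.12 and SLC7A5 by 1.42 ± 0.09. NF-kB targets were lower, 1 rose and 14 fell (1 and 17 adjusted over the list alone) of 31. Their median was -0.66 (-0.66, -0.37, -0.66), or -0.37 with dim members at their bound and -0.42 without DNMT1 replicate 3, with camera adjusted p = 1.0e-06, adjusted p = 0.32 with an estimated correlation. Secreted factors linked to senescence were lower too, 5 rose and 15 fell (5 and 20 adjusted over the list alone) of 34. Their median was -0.36 (-0.36, -0.35, -0.40), with camera adjusted p = 1.8e-06, adjusted p = 0.32 with an estimated correlation. Clustered protocadherins were also lower, 1 rose and 9 fell (1 and 9 adjusted over the list alone) of 16. Their median was -0.54 (-0.54, -0.63, -0.47), with camera adjusted p = 1.0e-04, adjusted p = 0.32 with an estimated correlation. TGF-beta targets were higher, 14 rose and 3 fell (16 and 3 adjusted over the list alone) of 36. Their median was 0.30 (0.30, 0.30, 0.35), with camera adjusted p = 5.1e-05, adjusted p = 0.32 with an estimated correlation. YAP and TEAD targets were higher, 11 rose and 1 fell (15 and 1 adjusted over the list alone) of 24. Their median was 0.24 (0.24, 0.30, 0.24), with camera adjusted p = 1.5e-04, adjusted p = 0.32 with an estimated correlation. LTBP1 rose by 0.87 ± 0.05 and LOX by 1.15 ± 0.10. In all, 4804 probes differed, 2431 higher and 2373 lower in DNMT3B (4987 with the slide as a block, 1635 within slide 1, 1077 within slide 2).

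The DNMT3B and DNMT3A lines differed most, at 10125 probes, 5078 higher and 5047 lower in DNMT3B (10435 with the slide as a block, 4987 within slide 1, 3095 within slide 2). HSPB2 was at least 96.0-fold (adjusted p = 1.6e-11) higher in the DNMT3B line, ME1 at least 39.9-fold, KRT14 at least 35.5-fold and DPPA4 at least 22.2-fold, and HHIP rose by 6.12 ± 0.19. HK2 was at least 52.3-fold (adjusted p = 6.6e-09) lower, VNN1 at least 46.4-fold and SAA2 at least 31.1-fold, BDKRB1 fell by 6.31 ± 0.20 and the prohormone processing enzyme CPE by 6.15 ± 0.11, with 3 of 4 DNMT3B arrays well above background. NF-kB targets were lower in DNMT3B, 0 rose and 26 fell (0 and 27 adjusted over the list alone) of 31. Their median was -1.89 (-1.89, -1.96, -1.63), or -1.63 with dim members at their bound, with camera adjusted p = 1.3e-16, adjusted p = 0.1 with an estimated correlation. IL11 fell by 3.34 ± 0.07 and CXCL5 by 2.82 ± 0.12. Secreted factors linked to senescence were also lower, 7 rose and 18 fell (7 and 18 adjusted over the list alone) of 34. Their median was -0.45 (-0.45, -0.47, -0.47), with camera adjusted p = 0.0016, adjusted p = 0.47 with an estimated correlation. So were interferon-stimulated genes, 8 rose and 22 fell (8 and 26 adjusted over the list alone) of 47. Their median was -0.30 (-0.30, -0.38, -0.21), with camera adjusted p = 2.5e-04, adjusted p = 0.6 with an estimated correlation. HLA-B fell by 2.02 ± 0.05. Epithelial genes were higher, 13 rose and 3 fell (13 and 3 adjusted over the list alone) of 30. Their median was 0.31 (0.31, 0.29, 0.23), with camera adjusted p = 0.0017, adjusted p = 0.32 with an estimated correlation. TGF-beta targets were higher, 18 rose and 7 fell (18 and 7 adjusted over the list alone) of 36. Their median was 0.35 (0.35, 0.29, 0.44), with camera adjusted p = 0.0029, adjusted p = 0.46 with an estimated correlation. YAP and TEAD targets were higher as well, 16 rose and 3 fell (16 and 3 adjusted over the list alone) of 24. Their median was 0.33 (0.33, 0.43, 0.26), with camera adjusted p = 2.5e-04, adjusted p = 0.32 with an estimated correlation. SPINT2 rose by 2.73 ± 0.12, TAGLN by 1.49 ± 0.08 and MYOF, a membrane repair protein, by 0.85 ± 0.06.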

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

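The splits of the arrays and the tests weighed for the NF-kB list and for the shared changes were chosen after the results were seen; the search for arrays that stand apart was not.

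Within each DNMT line, arrays far from the other 3 by Dixon's ratio (the gap to the nearest array over the range) were looked for in 5 measures per array and in each gene named. Chance alone sets apart about 1 in 20 groups. The 75th percentile of the intensity was 324 on DNMT3B replicate 2 against 286 to 288 on the other 3 arrays (ratio 0.950), and on the next principal component DNMT3B replicate 3 lay at -22.9 against -19.5 to -19.1 (ratio 0.879). Of 230 pairs of gene and line, 18 had an array apart, or 7.83%. In the DNMT1 line these were, with ratio and array, CSTA (0.849, replicate 3), CYP2J2 (0.913, replicate 1), DLL3 (0.872, replicate 2), KRT14 (0.877, replicate 4), LCE3A (0.883, replicate 1), LTBP1 (0.909, replicate 4), NLGN4X (0.929, replicate 2), PMVK (0.914, replicate 1), SAA2 (0.982, replicate 3) and SLC7A5 (0.872, replicate 2). In the DNMT3A line they were DMBT1 (0.83, replicate 4), HSPB2 (0.936, replicate 1), LEF1 (0.907, replicate 1) and MCM7 (0.912, replicate 1). In the DNMT3B line they were BATF (0.853, replicate 1), BDKRB1 (0.99, replicate 4), MEI1 (0.889, replicate 2) and PLAU (0.912, replicate 3).

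Other splits of the arrays of 2 lines into groups of the same sizes tested whether chance can give as many called probes. In all 6 comparisons the real split gave the most, 1 of 35. Chance differences between lines were not tested. The real counts and the highest of the other splits were 3259 and 35 for DNMT1 against GFP, 8057 and 2847 for DNMT3A and 1975 and 32 for DNMT3B. Between lines they were 7339 and 0 for DNMT3A against DNMT1, 4804 and 2 for DNMT3B against DNMT1, and 10125 and 3 for DNMT3B against DNMT3A. The splits closest to the slides called 0 probes in every comparison. All other splits mix lines, so line differences widen the spread, can lower counts and could hide a slide effect. For the probes changed alike in all 3 comparisons with GFP, 1 of 100 regroupings, the real one, gave as many (293, highest other 110). This argues against chance in how the arrays were grouped. Regroupings mix the lines, so they do not test what the shared GFP arrays add. For the number of gene lists called by camera, 5 of 100 regroupings gave as many (33, highest other 42), so chance was not excluded.

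The NF-kB list was higher than GFP in the DNMT3A line and lower in the DNMT3B line. A difference between the slides is argued against, since within each slide both medians kept their sign with a size of at least 0.44 (0.94 and -0.64 within slide 1, 0.44 and -0.87 within slide 2). Array scaling is argued against too, because over 4 other scalings the smallest size was 0.49. With 1 line per transgene, an inflammatory state of a single line that arose apart from its transgene cannot be told apart from an effect of the enzyme. A response to DNMT3A or DNMT3B therefore stays a hypothesis, and independent lines would be needed to test it.

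Probes changed in the same direction in all 3 DNMT lines may reflect chance values of the GFP arrays they share. Against that, of 88 probes called alike in all 3 on slide 1, 83 had that direction in all 3 on slide 2 (94.3%), where a different GFP array is used. The 3 comparisons on slide 2 share that array, which raises their agreement, and the share to be met without any change was not computed. A change in the single GFP line, in place of a change in the DNMT lines, would leave the DNMT lines alike. Of the 293 probes, 186 (63.5%) also differed between at least 2 of the DNMT lines, which neither excludes nor requires a GFP line that has drifted. A shared response to raised DNA methyltransferase activity stays open on the same footing.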

How the results depend on the processing

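The alternatives were fixed with the design; none was chosen after the results were seen. Over all alternatives, 4341 of the values of named genes kept their direction and their side of the threshold, 74 lost their call and 0 turned. All 223 named changes had every array of 1 group above every array of the other. Their direction therefore could not turn within a slide or without 1 array, and 0 turned is no test there. Those lost were 59 within slide 2, where the lone GFP array is assumed to vary like the other groups, 12 within slide 1, 2 with median centring (ODC1 in the DNMT3B line, adjusted p = 0.054, and PMVK in the DNMT1 line, 0.065) and 1 with only the 2 groups compared (DUSP4 in the DNMT3B line, 0.071). The calls lost within slide 2, all against GFP and at an adjusted p of 0.051 to 0.7 there, were those of ARF4, CBX2, CCNA2, CKS1B, COL15A1, DUSP4, ITGA5, ITGA6, KRT14, KRT16P2, LOX, LRIG1, LTBP1, MET, MUC1, PHGDH, PMVK, PRRX2, PSMD6, ROBO2, SCG2, SKIL, SLC3A2, SNAP25, TPX2, UBA3 and UNC5B in the DNMT1 line, DMBT1, FADS1, FDFT1, GRTP1, IDH2, IGFBP3, KCTD15, MAP2, NDRG1, PSMB9 and STARD4 in the DNMT3A line and AKR1C3, AREG, BEX1, CABP1, COL15A1, DUSP4, HLA-B, IDH2, IFITM1, KCTD15, MAGEA10, MAP2, MEGF6, MT1F, MX1, NXF3, ODC1, PCDHB6, PCDHB8, SAA2 and SNAP25 in the DNMT3B line. For arrays, signal over background is the limit, and dim probes have no measured fold. On the simulated arrays, changes under 2-fold were recovered in part.

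Fewer probes were called within either slide. Within slide 1, the counts were 1155 for DNMT1, 3775 for DNMT3A and 518 for DNMT3B against GFP, and 2756 for DNMT3A against DNMT1, 1635 for DNMT3B against DNMT1 and 4987 for DNMT3B against DNMT3A. Within slide 2, they were 284, 1156, 162, 1479, 1077 and 3095 in that order. Fewer arrays enter both fits. At least 2-fold changes numbered 741, 1461, 504, 1193, 970 and 1865 by construction. A plain t-test per probe, which does not share the spread between probes, called 2069 for DNMT1 and 881 for DNMT3B against GFP. Without the filter on dim probes, the overlap of all 3 comparisons was 193, that of DNMT1 with DNMT3B 377 and that of DNMT3A with DNMT3B 354, where more probes are tested and adjusted for.

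With arrays centred on their median, more calls were lower than higher in each comparison but that of DNMT3B with DNMT3A. This scaling gave 2540 (942 higher), 6192 (1890 higher) and 1478 (417 higher) against GFP, 5097 (2183 higher) for DNMT3A against DNMT1, 3387 (1667 higher) for DNMT3B against DNMT1 and 7922 (4416 higher) for DNMT3B against DNMT3A. It shifted the median of all probes by -0.11 for DNMT3A against GFP. The DNMT3A transcript in the DNMT3A line was 0.22 there (adjusted p = 0.21). It was 0.36 within slide 1 (adjusted p = 0.051) and 0.28 within slide 2. The cause was not tested.

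Leaving out 1 array at a time gave 2260 to 2937 probes for DNMT1, 5686 to 7608 for DNMT3A and 1284 to 1775 for DNMT3B against GFP, the lowest for DNMT3B without GFP replicate 3. Between lines it gave 5853 to 6903 for DNMT3A against DNMT1, 4010 to 4396 for DNMT3B against DNMT1 and 8764 to 10173 for DNMT3B against DNMT3A. The overlap of all 3 ran from 183 without GFP replicate 2, with 192 without GFP replicate 3, to 298. For pairs it ran from 1244 to 1879 for DNMT1 with DNMT3A, from 372 (GFP replicate 2; 375 without replicate 3) to 595 for DNMT1 with DNMT3B, and from 342 (GFP replicate 2; 355 without replicate 3) to 553 for DNMT3A with DNMT3B. The called lists numbered 31 to 37. The DNMT3A transcript ran from 0.30 to 0.35, that of DNMT1 from -0.15 to -0.09 and that of DNMT3B from -0.02 to 0.09.

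Among 91 list results followed, 0 of the 33 called against GFP stayed called by camera with an estimated correlation. There 4, 6 and 2 tests had an unadjusted p under 0.05, while fry called 13, 21 and 8. Calls against GFP that fry did not share were the G1/S list (adjusted p = 0.13) and the cholesterol list (0.16) in the DNMT1 line, and the G1/S (0.51), G2/M (0.16), cholesterol (0.19) and ribosome (0.076) lists in the DNMT3B line. The cholesterol list in the DNMT3B line turned to -0.0013 within slide 2 (0.19 over both slides; adjusted p of 1.7e-10 to 0.95 over its alternatives). Between lines, 10, 11 and 13 of the 34 lists passed camera for DNMT3A against DNMT1, DNMT3B against DNMT1 and DNMT3B against DNMT3A, and 0 with an estimated correlation (4, 6 and 6 at an unadjusted p under 0.05; fry called 24, 20 and 24). Of these 34 calls, 23 held with the slide as a block and within both slides. The interferon, YAP, hypoxia, unfolded protein and cholesterol lists (DNMT3A against DNMT1), the interferon and G1/S lists (DNMT3B against DNMT1), and the G1/S, G2/M, mesenchymal and cholesterol lists (DNMT3B against DNMT3A) lost theirs within a slide. Leaving out 1 array ended calls between lines as follows, with the adjusted p without that array. For DNMT3A against DNMT1 these were the interferon list (DNMT1 replicate 1, 0.059; DNMT3A replicate 1, 0.074), the unfolded protein list (DNMT1 replicates 1 and 4, 0.083 and 0.061; DNMT3A replicate 1, 0.23), the cholesterol list (DNMT1 replicate 1, 0.051), the YAP list (DNMT3A replicates 1, 2 and 3, 0.064, 0.072 and 0.051; DNMT1 replicate 4, 0.11) and the hypoxia list (DNMT3A replicate 3, 0.051). For DNMT3B against DNMT1 they were the interferon list (DNMT3B replicate 1, 0.057; DNMT1 replicate 4, 0.058), the G1/S list (DNMT1 replicates 2 and 3, 0.19 and 0.16; DNMT3B replicates 2 and 4, 0.10 and 0.069) and the lysosome list (DNMT1 replicate 4, 0.061). For DNMT3B against DNMT3A they were the cholesterol list (DNMT3B replicate 1, 0.064) and the mesenchymal list (DNMT3A replicate 4, 0.082). Over the alternatives at the preset correlation the adjusted p of these 10 lists ran from 6.2e-06 to 0.47, and none of these calls is stated as a result. Against GFP, calls appeared for the YAP list in the DNMT1 line without GFP replicate 1 (adjusted p = 0.040) or DNMT1 replicate 4 (0.011). In the DNMT3A line calls appeared for the G2/M list without DNMT3A replicate 1 (0.0078; 0.0033 to 0.94 over its alternatives) and for the G1/S list without DNMT3A replicate 1 (9.8e-05) or GFP replicate 2 (0.040; 9.8e-05 to 1.00 over its alternatives).

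With the title number as a replicate block, counts were 3875, 9730 and 2360 against GFP and 8345, 5497 and 11247 between lines, overlaps 395, 2291, 718 and 752 (all 3, DNMT1 with DNMT3A, DNMT1 with DNMT3B, DNMT3A with DNMT3B), and 36 lists were called. With the code number as a block they were 4071, 9197, 2545, 8929, 5867 and 11787, with overlaps of 406, 2275, 794 and 751 and 36 lists. The DNMT1, DNMT3A and DNMT3B transcripts in their own lines were -0.16, 0.31 and 0.02 with the title block and -0.13, 0.37 and 0.06 with the code block. The pairs correlated at -0.11 to 0.43, and 7 of 15 arrays correlated best with their own title number in every other group and 11 of 15 with their own code number, a hint from the data only. The title block ended the YAP call in the DNMT3B line (0.11, adjusted p = 0.064, range 0.0036 to 0.37). It gave one in the DNMT1 line (-0.12, adjusted p = 0.017, range 0.011 to 0.17). The code block ended the interferon call between DNMT3A and DNMT1 (0.10, adjusted p = 0.054, range 4.7e-04 to 0.46). These ranges are over alternatives at the preset correlation, and no other call among these results changed.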

Other observations

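The tests of the run on chromosome 3 were chosen after the result was seen; the gene lists were fixed with the design.

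Of the 34 lists, 15 did not pass camera in any comparison with GFP (adjusted p from 0.065 to 0.98), and in most of them members moved both ways. Counts are given for the DNMT1, DNMT3A and DNMT3B lines in that order. Of 17 germline and cancer-testis genes, 1, 5 and 4 rose and 2, 3 and 1 fell (1, 6 and 4, and 2, 3 and 1, adjusted over the list alone). In the DNMT3A line MAGEC1 rose by 3.48 ± 0.23 while MAGEC2, its near relative, fell by 3.39 ± 0.12. SSX1 rose by 2.27 ± 0.18 in the DNMT1 line and fell by 2.63 ± 0.18 in the DNMT3A line, with 3 of 4 DNMT3A arrays well above background. Of 27 imprinted genes, 4, 4 and 3 rose and 3, 5 and 1 fell (5, 4 and 3, and 4, 5 and 1, adjusted over the list alone). MEST was at least 6.1-fold higher in the DNMT1 line and below background in the other 3 lines, so its falls in the counts for the DNMT3A and DNMT3B lines are no measured change. CDKN1C, an inhibitor of the cell cycle, fell by 2.36 ± 0.23 in the DNMT3A line. Of 29 homeobox genes, 5, 6 and 3 rose and 4, 5 and 2 fell (5, 6 and 4, and 5, 6 and 4, adjusted over the list alone). PRRX2, of limb and skin mesenchyme, fell by 4.62 ± 0.14 in the DNMT3A line and by 1.05 ± 0.14 in the DNMT1 line, and HOXC4 was at least 4.44-fold higher in the DNMT3A line. Of 26 genes of DNA methylation, 1, 5 and 1 rose and 3, 5 and 0 fell (2, 5 and 1, and 3, 5 and 0, adjusted over the list alone). IDH2, the mitochondrial isocitrate dehydrogenase, rose by 0.84 ± 0.10 in the DNMT3A line and 0.65 ± 0.10 in the DNMT3B line. Within slide 1 the call in the DNMT3B line was lost (adjusted p = 0.098), and within slide 2 both were (0.073 and 0.30).

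The acinar, ductal and endocrine lists and that of endothelial, immune and neural markers gave no call. Of 11 acinar genes, 2, 2 and 0 rose and 0, 1 and 2 fell (2, 2 and 0, and 0, 1 and 2, adjusted over the list alone). The trypsinogens PRSS2 and PRSS3, near-identical genes whose signals are not separated here, rose by 1.40 ± 0.10 and 1.32 ± 0.10 in the DNMT1 line and fell by 3.25 ± 0.10 and 2.65 ± 0.10 in the DNMT3B line. Of 14 ductal genes, 2, 4 and 1 rose and 3, 3 and 2 fell (3, 4 and 1, and 3, 3 and 3, adjusted over the list alone), where SOX9, counted as a fall in the DNMT3B line, was below background there and in the GFP line. Of 15 endocrine genes, 2, 3 and 0 rose and 1, 0 and 0 fell (3, 3 and 0, and 1, 0 and 0, adjusted over the list alone). The granule protein SCG2 was at least 3.91-fold higher and SCG5 fell by 2.92 ± 0.18 in the DNMT1 line. Of 13 endothelial, immune and neural markers, 2, 1 and 2 rose and 1, 3 and 2 fell (2, 1 and 2, and 1, 3 and 2, adjusted over the list alone). SNAP25, of synaptic release, rose by 1.28 ± 0.11 in the DNMT1 line and fell by 0.88 ± 0.11 in the DNMT3B line. MAP2, which binds microtubules, fell by 1.06 ± 0.11 in the DNMT3A line and rose by 1.06 ± 0.11 in the DNMT3B line. Of 26 RAS and MAPK feedback genes, 2, 4 and 0 rose and 3, 9 and 3 fell (2, 4 and 0, and 4, 11 and 3, adjusted over the list alone). The phosphatase DUSP4 rose by 0.99 ± 0.09 and 1.00 ± 0.09 in the DNMT1 and DNMT3A lines. In the DNMT3B line it fell by 0.46 ± 0.09, a call lost with only the 2 groups compared (adjusted p = 0.071), within slide 1 (adjusted p = 0.066) and within slide 2 (-0.30, adjusted p = 0.70). Of 38 hypoxia and glycolysis genes, 2, 11 and 1 rose and 3, 4 and 2 fell (2, 14 and 1, and 3, 4 and 3, adjusted over the list alone), and NDRG1 rose by 1.03 ± 0.11 in the DNMT3A line. Of 33 p53 targets, 2, 11 and 1 rose and 7, 5 and 1 fell (3, 14 and 2, and 7, 7 and 1, adjusted over the list alone). Of 26 immediate-early genes, 0, 4 and 0 rose and 0, 3 and 3 fell (0, 5 and 0, and 0, 4 and 3, adjusted over the list alone). Of 35 lysosome genes, 3, 5 and 0 rose and 0, 6 and 1 fell (1, 5 and 0, and 0, 6 and 0, adjusted over the list alone). Of 39 respiratory chain genes, 0, 5 and 0 rose and 1, 0 and 0 fell (0, 4 and 0, and 0, 0 and 0, adjusted over the list alone). Of 14 housekeeping genes, 0, 3 and 0 rose and 0, 1 and 0 fell (0, 3 and 0, and 0, 1 and 0, adjusted over the list alone).

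Some transcripts were well above background in 1 line alone of a pair. Called probes above background on every array of the DNMT line and on no GFP array numbered 104, 184 and 40 for DNMT1, DNMT3A and DNMT3B, and the opposite held for 49, 140 and 66. In 23 of the 102 list tests against GFP the median, the mean and the direction of the test differed in sign, and camera called 0 of these 23 and 33 of all 102.

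A run of neighbouring genes on chromosome 3 was lower in the DNMT1 line. It covers 56653364 to 71008467 (hg19), from CCDC66 to FOXP1, and was found by the lowest median over 25 neighbouring genes among 19167 genes in order. Of 49 genes in it 31 fell and 0 rose by limma, and 42 lay below 0 (85.7%), with a median of -0.54 (median absolute deviation 0.31) against 0.07 in the DNMT3A line and 0.05 in the DNMT3B line, and -0.02 in 100 flanking genes. Of its genes, named after their values were seen, limma called falls in the proteasome subunit PSMD6 (-0.68 ± 0.08), the NEDD8-activating subunit UBA3 (-0.75 ± 0.06), the small GTPase ARF4 (-0.71 ± 0.06) and LRIG1 (-1.15 ± 0.08). LRIG1 was also lower in the DNMT3A and DNMT3B lines (-0.71 and -0.43). Against 100 random orders of each line's own values, the DNMT3B line also had a lower run, on chromosome 4 (-0.32 against -0.16). Higher runs lay among small nucleolar RNA genes of chromosome 14 in the DNMT3A line (0.50 against 0.36) and the DNMT3B line (0.29 against 0.26), and on chromosome 8 in the DNMT1 line (0.2536 against 0.2535). The lowest run of the DNMT3A line was within the random orders (-0.24 against -0.33).

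The genes of the run were picked for being low, so the run is a hypothesis of regional loss. Chance clustering is argued against, as the lowest such median in 100 random gene orders was -0.22. Array scaling and the slides are argued against, since the median nearest to 0 over the scalings and within each slide was -0.43. Loss of 1 of 2 copies may explain a fall of this size, but the median of -0.54 cannot be told apart from silencing of the region or from a line that began with fewer copies, because expression alone was measured. DNA from the lines would be needed to test it.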
